A study of Homo sapiens with 12 samples.

How the data were processed

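The series holds 12 libraries in 6 groups of 2, assigned from the sample titles: Hi-C, polyA RNA-seq and ChIP-seq. Deposited files of expected counts, changed genes and peaks were read, and the Hi-C data are not analysed here. No column of per-sample values was left without a sample.

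The count table holds expected counts per gene for the 4 RNA-seq libraries, estimated by the authors with RSEM 1.2.7 on hg19, per the submitters' processing notes, which also name Bowtie; the roles of the tools are not given in the sources used here. Per the labels' protocols, the libraries were polyA-selected, unstranded and sequenced as 100 nt single-end reads, from cells at 75% confluency. RSEM shares reads between similar genes by estimation, so paralogs and processed pseudogenes can exchange counts, and unstranded reads of overlapping genes cannot be told apart. The table has 26488 genes, of which 80.6% have a symbol that matched the reference tables, and 23 symbols had been turned into dates. The authors' deposited table of changed genes holds, per the file headers, base means, log2 fold changes with standard errors, test statistics and p-values in the column layout of DESeq2, which the submitters' processing notes name together with R 3.1.0. Its base mean is a signal averaged over the libraries by the authors. Its minus signs were written in an encoded form at 4236 places and were decoded before use. From the values, it keeps genes with adjusted p under 0.01 (highest 0.009996) and an absolute log2 fold change of at least 1. The deposited peak list is a single list for 2 BRG1 pulldown and 2 input libraries. The submitters' processing notes name Bowtie2, HOMER and hg19 for it, and how the replicates were combined is not given in the sources used here. The score that the authors' peak list gives each peak is 1 throughout and was not used. Per the labels' protocols, chromatin was crosslinked for 10 minutes.

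Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr at its defaults, libraries were scaled by TMM, and shBRG1 was compared with shSCRAM by edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled, and standard errors of log2 fold changes were derived from the F statistic. Depth ran from 13299160 to 47052163 expected counts per library. In counts simulated from these libraries over 14622 genes, the edgeR step called 70.8% of 96 genes changed 1.5-fold and 87.9% of 66 changed 2-fold. It called 95.3% of 64 changed 4-fold and 0.0486% of 14396 unchanged genes. That simulation drew all libraries with the same dispersion trend. The real pairs differed in biological coefficient of variation (2.24% for shSCRAM and 13.7% for shBRG1), and 51.2% of tested genes passed. The simulated rates therefore need not hold for the real calls.

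A total of 29 gene lists was fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. Of these, 28 had at least 5 tested members, and the list of mitochondrially encoded genes matched no row. Lists were tested by camera (limma 3.58.1) on log-CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 28 lists. The rule named SMARCA4 and SMARCA2, the 12 genes with the largest change in each direction among those past the threshold with non-overlapping groups and at least 5 CPM in the higher group, and in each list up to 4 members past the threshold with the smallest p; for list members described as not changed it took the 2 most highly expressed. Outside this rule, FN1, VIM, KRT5, PKM and C3 are named as the most highly expressed members of their lists although they passed, COL1A1, COL1A2 and COL3A1 for a test, and SNAI1 after its value was seen. The part of the rule that ranks peaks by score could not be applied, because the score is constant.

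The replicates were compared before averaging. Over genes with at least 100 counts in a pair, the chi-square per gene was 2.59 for the shSCRAM pair and 21.2 for the shBRG1 pair, so both pairs differed beyond counting noise. Each library was counted as a sample, which does not show that the libraries are separate cultures. Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, other scalings, other filters, unrounded counts, other thresholds, a replicate block, each library left out in turn, and for the lists an estimated correlation and fry. Added after seeing the data were a composition covariate, thinning all libraries to the lowest total, the shSCRAM libraries summed as 1 sample, and limma-voom with a quality weight per group. The composition covariate is the median log-CPM of 26 long GC-rich transcripts minus that of 31 long AT-rich transcripts, lists written from general knowledge without sequence. It was -0.37 and -0.40 in the shSCRAM libraries, 1.06 in shBRG1 replicate 1 and 1.89 in replicate 2.

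Peaks were described by number, width and spacing with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures drawn with matplotlib 3.10.9. The planned test of peaks at the promoters of changed genes was not run, since an hg19 gene annotation is not used here. Gene order along chromosomes, without coordinates, was taken from the RefSeq table of GRCh38.p14 for 20941 genes.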

Results

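The series covers MCF-10A, a non-tumorigenic human mammary epithelial cell line, in which a doxycycline-induced short hairpin lowered SMARCA4. This gene encodes BRG1, an ATPase subunit of the SWI/SNF chromatin remodelling complexes. Cells with a scrambled hairpin (shSCRAM) served as the control, and both lines received 0.05 µg/ml doxycycline for 3 to 4 days. The labels name no other hairpin against SMARCA4, no rescue and no uninduced cells of either line. The reduction of SMARCA4 therefore cannot be told apart from other effects of the hairpin or from differences between the lines. The data used here hold no measure of BRG1 protein in the hairpin lines. The 12 libraries comprised 4 Hi-C libraries, 4 polyA RNA-seq libraries with 2 per hairpin, and 4 ChIP-seq libraries of the parental cells with 2 BRG1 pulldowns and 2 inputs. The Hi-C libraries are not analysed here. The RNA-seq libraries held 47052163 (shSCRAM replicate 1), 36234504 (shSCRAM replicate 2), 13299160 (shBRG1 replicate 1) and 35556565 (shBRG1 replicate 2) expected counts. The deepest library thus held 3.54 times the counts of the shallowest. Expression was given in CPM (counts scaled to a common library total) after trimmed-mean scaling, each value as mean ± SD over 2 libraries unless single libraries are named. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

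The hairpin target was examined first. SMARCA4 stood at 154 ± 2.87 CPM (SD, n = 2) in shSCRAM and at 65.3 ± 0.280 CPM (SD, n = 2) in shBRG1 cells. Its log2 fold change was -1.24 with a standard error of 0.09, and it passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.00038. Both shBRG1 libraries (65.1 and 65.5 CPM) lay below both shSCRAM libraries (156 and 152 CPM). The authors' deposited table lists a log2 fold change of -1.21 for the same gene. SMARCA2, which encodes BRM, the alternative ATPase of the complex, was at 61.8 ± 1.86 CPM in shSCRAM and 59.5 ± 5.07 CPM in shBRG1 cells, a log2 difference of -0.06 that did not pass the test (edgeR adjusted p = 0.66). Without shBRG1 replicate 1 that difference was -0.12. A single shBRG1 library was left there, so the spread of that group could not be measured.

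**Figure D1:**
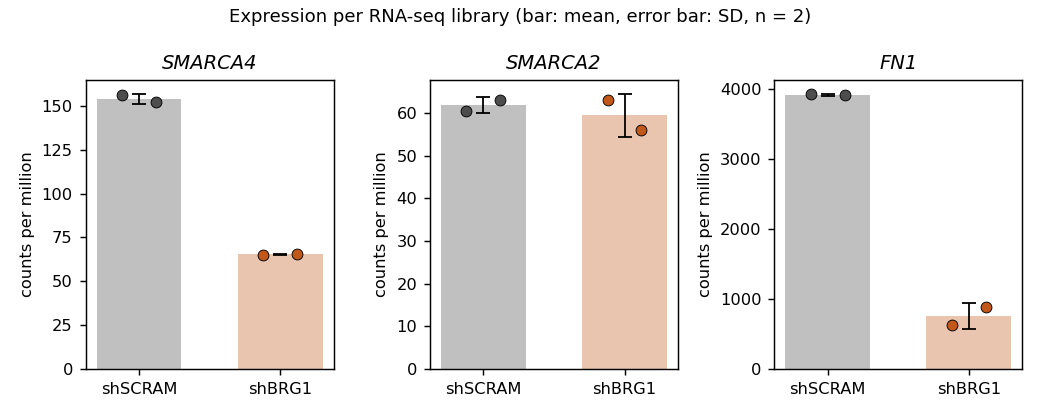
CPM (vertical axes, starting at 0) of SMARCA4, SMARCA2 and FN1 in the shSCRAM and shBRG1 RNA-seq libraries. Points are single libraries, bars the mean and error bars the SD over 2 libraries. SMARCA4 averaged 154 CPM in shSCRAM and 65.3 CPM in shBRG1 cells, and FN1 averaged 3915 and 757 CPM.

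The RNA-seq comparison asked which transcripts differed between knockdown and control cells. Among the largest decreases were CFH, an inhibitor of the complement cascade, from 12 ± 0.491 to 0.610 ± 0.105 CPM, and KIF26A, a kinesin family member, from 21.4 ± 1.43 to 1.27 ± 0.177 CPM. ZEB1, a transcriptional repressor of epithelial genes, fell from 13.3 ± 1.26 to 0.940 ± 0.355 CPM (log2 fold change -3.68), and AKAP12, a kinase-anchoring protein, from 278 ± 4.48 to 22.9 ± 7.81 CPM. POSTN (periostin, a matrix protein), IL33 and its receptor gene IL1RL1, MUC5AC, NEGR1, PTPN22, CLGN and SYCP2 completed the 12 largest decreases, with log2 fold changes from -3.97 (IL33) to -3.27 (PTPN22) apart from CLGN at -4.21. Among the largest increases, ETNK2, an ethanolamine kinase, rose from 12.96 ± 0.397 to 89.8 ± 15.2 CPM, and WFDC2 from 22.6 ± 0.226 to 111 ± 7.97 CPM. KCNK5, a potassium channel, rose from 44.7 ± 1.26 to 159 ± 14.01 CPM. SERPINA3, a secreted protease inhibitor, rose from 196 ± 0.503 to 665 ± 193 CPM, and the imprinted non-coding RNA H19 from 21.7 ± 1.18 to 68.7 ± 16.6 CPM. SCD, the stearoyl-CoA desaturase, rose from 635 ± 9.17 to 1992 ± 154 CPM. STAC2, HLA-DOB, KIAA1683, ARHGEF16, IRF9 and REC8 also belonged to the 12 largest increases. IRF9 was at 17.9 CPM in shBRG1 replicate 1 and 3.96 CPM in replicate 2, and REC8 at 7.27 and 3.66 CPM. HLA-DOB was at 15.9 and 6.82 CPM. These genes differed widely between the shBRG1 libraries, so their levels are uncertain. IRF9 and REC8 also lie close together on the chromosome, and whether they share reads was not tested.

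In all, 7600 of 14849 tested genes passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg, two-sided), 3674 higher and 3926 lower in shBRG1 cells. The larger changes were mostly decreases: 1845 genes were at least 2-fold lower and 236 at least 2-fold higher, so that 88.7% of the 2-fold calls were lower. Groups did not overlap for 78.9% of the tested genes, where chance gives 33.3%. With library totals in place of the trimmed-mean scaling the split became 2676 higher and 4394 lower, since the median of all genes then moved by -0.11 on the log2 scale. Without shSCRAM replicate 1 the count was 3311 (904 higher, 2407 lower), and without shSCRAM replicate 2 it was 3469 (999 higher, 2470 lower). The shSCRAM pair differed by a biological coefficient of variation of 2.24% and the shBRG1 pair by 13.7%, so the pooled estimate rests on unequal pairs.

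The shBRG1 libraries also stood apart from each other. Across 9472 genes above 8 CPM, which are not independent replicates, the log2 difference between the shBRG1 libraries correlated with the fold change at r = 0.64, and that between the shSCRAM libraries at r = -0.02. Base composition was not measured from sequence. Long transcripts chosen from general knowledge as rich in A and T (31 tested, such as ATM, EEA1 and TMF1) had a median log2 fold change of -1.61, and all 31 were lower past the threshold. Long transcripts chosen as rich in G and C (26 tested, such as AHDC1, POLRMT and CAPN1) had a median of 0.38, with 17 higher and 0 lower. Both lists were written after the fold changes had first been seen. Between the 2 shBRG1 libraries, which share a condition, the AT-rich list was lower in replicate 2 than in replicate 1 by a median of -0.63 and the GC-rich list higher by 0.17, whereas in the shSCRAM pair the medians were 0.03 and -0.02. Collagens and mesenchymal markers, although lower in shBRG1 cells like the AT-rich list, were higher in replicate 2 like the GC-rich list, by medians of 0.27 and 0.22. When the difference between the lists in each library was added to the edgeR fit as a covariate, a choice made after seeing the data, 2119 genes passed (1329 higher, 790 lower), of which 1082 were also called in the same direction without it. The slope of that covariate rests almost wholly on the 2 shBRG1 libraries. The fit also leaves less to measure spread with. Over 78 collagen, matrix glycoprotein and mesenchymal genes the median standard error went from 0.14 to 0.25. A call lost under the covariate, here and below, therefore need not mean a smaller change. The covariate ended the calls of CLGN, SYCP2, IL33, KIAA1683 and H19 among the 12 largest changes in each direction, and those of AHDC1, POLRMT and CAPN1. The log2 fold changes there were -0.68, -0.49, -3.43, 0.76, 0.53, 0.45, 0.42 and 0.18 in the order given, against -3.97 for IL33 without the covariate.

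**Figure D2:**
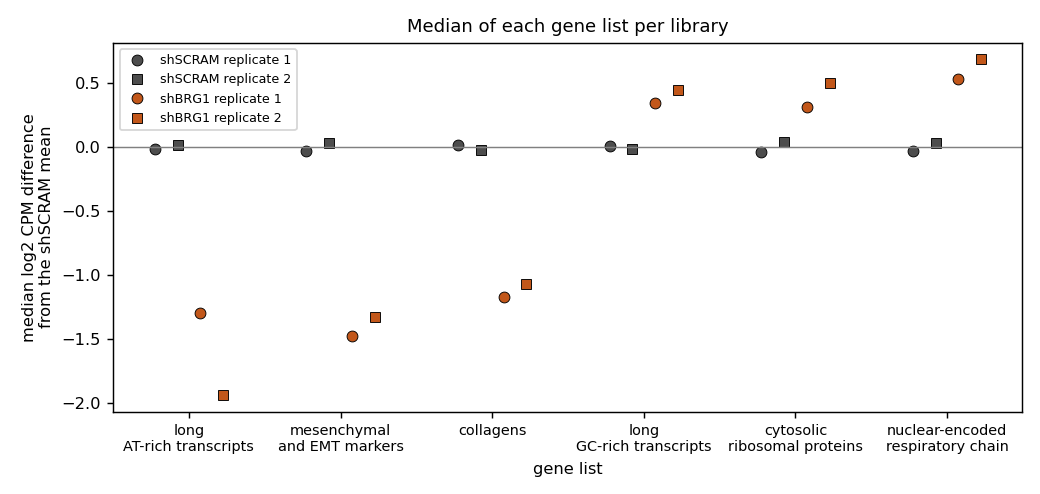
Median difference in log2 CPM from the shSCRAM mean (vertical axis) of 6 gene lists (horizontal axis) in each RNA-seq library, with a point per library. The AT-rich list lay at -1.30 in shBRG1 replicate 1 and -1.94 in replicate 2, while collagens lay at -1.18 and -1.07.

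Genes of the extracellular matrix and of mesenchymal cells were lower in the knockdown. Of 20 tested mesenchymal and EMT markers, 16 fell, 1 rose and 3 did not pass, with a median log2 fold change of -1.44. Besides ZEB1, CDH2, which encodes N-cadherin, fell from 28.2 ± 1.70 to 4.74 ± 0.203 CPM, VIM (vimentin) from 492 ± 19.0 to 169 ± 26.3 CPM, and FAP, a membrane protease, from 73.4 ± 3.14 to 15.5 ± 2.82 CPM. The 1 that rose was SNAI1, a transcriptional repressor, with a log2 fold change of 1.30, named because it was alone. Of 38 basement membrane and matrix glycoproteins, 22 fell and 2 rose, with a median of -0.62. Fibronectin (FN1) fell from 3915 ± 15.1 to 757 ± 188 CPM, and the authors' deposited table gives it a log2 fold change of -2.20. NID2, a basement membrane linker, fell from 29.1 ± 0.783 to 5.97 ± 0.110 CPM, and POSTN from 64.1 ± 2.30 to 5.92 ± 1.26 CPM. Of 21 collagens, 14 fell and 1 rose, with a median of -1.20. COL7A1, the anchoring fibril collagen, fell from 127 ± 11.6 to 49.0 ± 6.45 CPM, while the epithelial COL17A1 was at 401 ± 7.37 and 427 ± 51.7 CPM and did not pass. Of 34 matrix proteases, inhibitors and crosslinkers, 15 fell and 3 rose, with a median of -0.45. SERPINE2 fell from 550 ± 3.03 to 157 ± 0.694 CPM, the collagen crosslinking enzyme LOX from 410 ± 5.21 to 169 ± 10.2 CPM, and the lysyl hydroxylase PLOD2 from 428 ± 5.87 to 116 ± 21.8 CPM.

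The counts adjusted over the list alone were 18 of 20 mesenchymal markers, 25 of 38 glycoproteins, 15 of 21 collagens and 18 of 34 proteases and crosslinkers. By camera on log-CPM with a preset inter-gene correlation of 0.01, the adjusted p over 28 lists was 3.6e-05 for the mesenchymal markers, 3.6e-05 for the glycoproteins, 0.0031 for the collagens and 0.0082 for the proteases. None of the 28 lists passed camera when the correlation was estimated. The adjusted p with an estimated correlation was 0.54 for the mesenchymal markers, the glycoproteins and the collagens, and 0.56 for the proteases. So few libraries leave too little to estimate the correlation from. Even the AT-rich list, with all 31 members lower, had an adjusted p of 0.57 with an estimated correlation. The respiratory chain list, with 39 of 42 members higher, had 0.54. That setting therefore cannot decide, here and below, whether a list changed. The AT-rich transcripts fell in the same libraries, by a median of -1.61. Under the covariate the medians were -1.50, -0.95, -1.20 and -0.85 in the order given, and 13 of the 17, 18 of the 24, 6 of the 15 and 10 of the 18 called members kept their call and direction. Without shBRG1 replicate 1 the protease list no longer passed (camera adjusted p = 0.069).

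**Figure D3:**
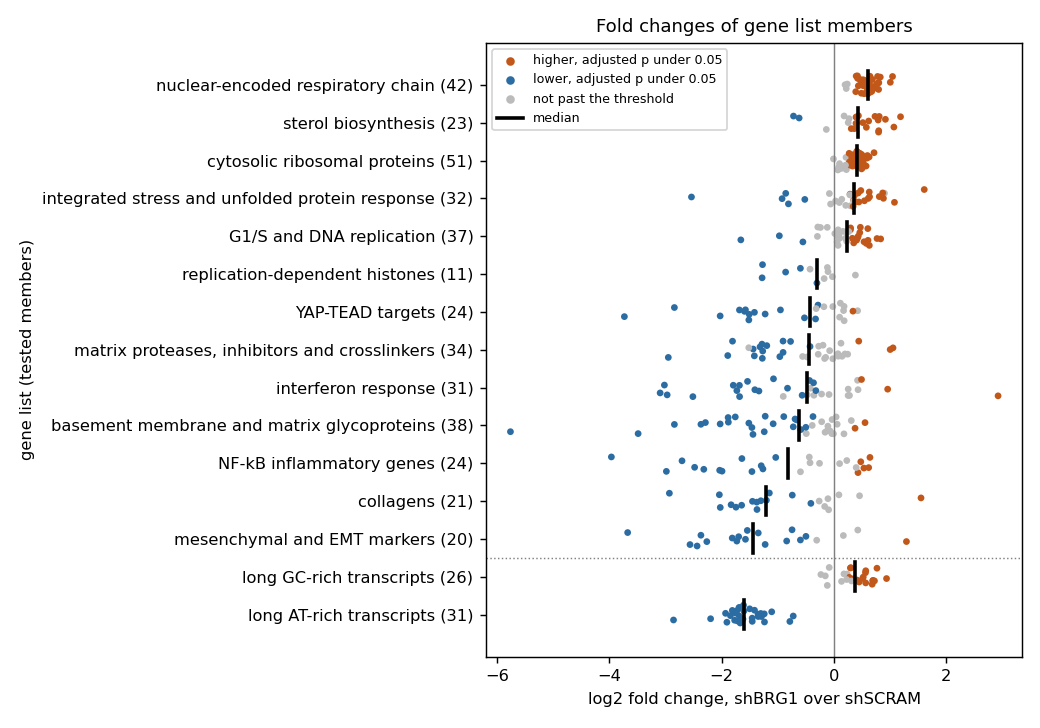
Log2 fold change of shBRG1 over shSCRAM (horizontal axis) of each tested member of 13 gene lists past the camera threshold and of 2 composition lists below the dotted line. Points are genes, coloured by edgeR call, and black bars the list medians, from -1.44 for mesenchymal and EMT markers to 0.60 for the respiratory chain among the 13 lists.

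Targets of the YAP and TEAD transcription factors fell in 14 of 24 cases and rose in 1, with a median of -0.42 (16 past when adjusted over the list alone). CTGF, a secreted matrix-associated protein, fell from 127 ± 1.49 to 17.4 ± 2.57 CPM, CYR61 from 41.6 ± 0.654 to 10.3 ± 0.517 CPM and IGFBP3 from 838 ± 6.98 to 294 ± 25.9 CPM. CTGF, CYR61 and IGFBP3 are also in the list of matrix glycoproteins, so these lists are not independent. The camera adjusted p of the YAP and TEAD list was 0.0049, and the adjusted p = 0.54 with an estimated correlation. Of 20 TGF-beta response genes, 11 fell and 5 rose, 16 passing when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.16). SERPINE1, also in the list of matrix proteases and inhibitors, fell from 236 ± 5.30 to 88.1 ± 17.9 CPM and the ligand gene TGFB2 from 57.2 ± 0.206 to 18.0 ± 2.63 CPM. The covariate left 11 of the 15 YAP and TEAD calls and 7 of the 16 TGF-beta calls in the same direction. The YAP and TEAD median went from -0.42 to -0.48 and the TGF-beta median from -0.34 to -0.37. The TGF-beta list passed camera there. Interferon response genes fell in 17 of 31 cases and rose in 3, with a median of -0.47 (23 past when adjusted over the list alone; camera adjusted p = 0.0035). IFI44L fell from 41.6 ± 1.38 to 5.52 ± 2.26 CPM and GBP1 from 24.1 ± 1.62 to 7.65 ± 1.09 CPM. For this list the adjusted p = 0.54 with an estimated correlation, and the composition covariate left 2 of the 20 calls in the same direction, IFI44L and GBP1 not among them. The median there was -0.53, and the list passed camera. NF-kB inflammatory genes fell in 12 of 24 cases and rose in 5, with a median of -0.81 (18 past when adjusted over the list alone; camera adjusted p = 0.039). IL1A, encoding interleukin-1 alpha, fell from 10.98 ± 0.538 to 1.34 ± 0.165 CPM, while complement C3 rose from 680 ± 21.1 to 1047 ± 134 CPM. This list missed the threshold without either shBRG1 library (camera adjusted p = 0.081 without replicate 1 and 0.10 without replicate 2) and with library totals (0.074), and had an adjusted p = 0.54 with an estimated correlation. Its median was -0.20 under the covariate, with 2 members higher and 2 lower and 3 of the 17 calls left in the same direction, and the list passed camera there. Replication-dependent histones, whose transcripts mostly lack polyA tails, fell in 5 of 11 cases (4 when adjusted over the list alone), with a camera adjusted p of 0.046 and adjusted p = 0.54 with an estimated correlation. HIST1H2AC was at 7.41 ± 0.550 and 4.88 ± 0.0827 CPM. These histone genes are near-identical copies, so their counts are uncertain, and the list call was lost without either shSCRAM library (camera adjusted p = 0.15 without replicate 1 and 0.090 without replicate 2) and without shBRG1 replicate 1 (0.22), and also with a replicate block (0.0998), with relative log expression (0.0504) and upper-quartile scaling (0.0559), with the shSCRAM libraries summed (0.085), and with no filter beyond a count above 0 (0.70, median -0.11). Under the covariate the list passed camera with a median of -0.66, and 0 of the 5 calls were left.

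Genes of oxidative metabolism, sterol synthesis and translation were higher in the knockdown. Of 42 nuclear-encoded respiratory chain genes, 39 rose and 0 fell, with a median of 0.60 (40 past when adjusted over the list alone). CYC1, encoding cytochrome c1, rose from 298 ± 1.69 to 616 ± 78.4 CPM, and SDHB, a succinate dehydrogenase subunit, from 150 ± 2.48 to 252 ± 2.21 CPM. Of 51 cytosolic ribosomal protein genes, 40 rose and 0 fell, with a median of 0.42 (40 past when adjusted over the list alone). RPS2 rose from 2218 ± 62.3 to 3649 ± 485 CPM and RPLP2 from 405 ± 11.7 to 578 ± 41.0 CPM, and since ribosomal protein genes have many processed pseudogenes their counts are uncertain. Of 23 sterol biosynthesis genes, 17 rose and 2 fell, with a median of 0.44 (20 past when adjusted over the list alone). MVD, an enzyme of the mevalonate pathway, rose from 70.2 ± 0.236 to 148 ± 3.42 CPM and LSS, the lanosterol synthase, from 115 ± 1.18 to 218 ± 14.4 CPM. The camera adjusted p was 2.0e-11, 5.0e-08 and 7.9e-05, and adjusted p = 0.54, 0.56 and 0.54 with an estimated correlation, in the order given. The GC-rich transcripts rose in the same libraries, by a median of 0.38. Under the covariate, the ribosomal protein genes had a median of 0.00010 with 1 higher and 1 lower, the respiratory chain genes 0.34 with 15 higher, and the sterol genes 0.53 with 11 higher. The calls left in the same direction were 0 of 40, 12 of 39 and 8 of 19.

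Stress and cell cycle genes moved less evenly. Of 32 genes of the integrated stress and unfolded protein responses, 17 rose and 5 fell, with a median of 0.36 (22 past when adjusted over the list alone; camera adjusted p = 0.0033, and adjusted p = 0.54 with an estimated correlation). TRIB3 rose from 20.1 ± 0.701 to 61.2 ± 10.2 CPM and the asparagine synthetase gene ASNS from 23.9 ± 0.177 to 50.5 ± 2.30 CPM, while the cystine transporter gene SLC7A11 fell from 108 ± 2.12 to 19.2 ± 7.76 CPM. The composition covariate ended the call of this list (median 0.21, camera adjusted p = 0.12), with 6 of the 22 calls left in the same direction. Of 37 genes of G1/S and DNA replication, 17 rose and 3 fell, with a median of 0.23 (21 past when adjusted over the list alone; camera adjusted p = 0.0033, and adjusted p = 0.56 with an estimated correlation). CDT1, a replication licensing factor, rose from 34.0 ± 0.121 to 60.7 ± 2.37 CPM and MCM7 from 203 ± 2.19 to 303 ± 2.14 CPM, while the cyclin gene CCNE2 fell from 41.2 ± 1.49 to 13.6 ± 5.52 CPM. Without shBRG1 replicate 1 this list no longer passed (camera adjusted p = 0.063), and under the covariate it passed with a median of 0.57, 21 members higher and 0 lower. Of 34 G2/M and mitosis genes, 14 rose and 13 fell, 28 passing when adjusted over the list alone, with a camera adjusted p of 0.48. The kinase gene PLK1 rose from 137 ± 1.29 to 216 ± 4.60 CPM, whereas CENPE, a kinesin of the kinetochore that is also in the AT-rich list, was at 69.6 ± 0.722 and 15.9 ± 7.60 CPM. Under the covariate 18 of these mitotic genes were higher and 0 lower, and the list passed (camera adjusted p = 1.2e-05). That slope rests on the 2 shBRG1 libraries, between which these genes differed by a median of -0.23 (replicate 2 against replicate 1). Of the calls without the covariate, 9 of 20 G1/S and 8 of 27 mitotic ones kept their call and direction.

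Among chromatin genes, no list passed camera. Of 26 SWI/SNF subunits, 7 rose and 6 fell, 13 passing when adjusted over the list alone (camera adjusted p = 0.34). Besides SMARCA4, SMARCD2 rose from 122 ± 1.24 to 251 ± 23.1 CPM, while SMARCC1 was at 170 ± 1.44 and 185 ± 16.5 CPM and did not pass. The composition covariate left 3 of the 13 subunit calls in the same direction, while the subunit median went from 0.12 to 0.13. Of 20 other remodeler ATPases, 4 rose and 11 fell, 16 passing when adjusted over the list alone (camera adjusted p = 0.17), including ATRX, from 111 ± 0.0227 to 25.3 ± 6.72 CPM. Of 24 genome architecture proteins, 6 rose and 13 fell, 20 passing when adjusted over the list alone (camera adjusted p = 0.27), including the cohesin gene SMC3, from 95.2 ± 0.261 to 33.7 ± 8.16 CPM. The composition covariate left 2 of the 15 remodeler calls and 3 of the 19 architecture calls in the same direction, and ended that of SMC3. The remodeler median went from -0.48 to -0.02, and the architecture median turned from -0.53 to 0.31, with 7 members higher and 1 lower. The AT-rich list fell by a median of -1.61 in the same libraries.

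Epithelial adhesion genes were mixed. Of 31 cell-cell junction genes, 15 rose and 7 fell, with a median of 0.27 (22 past when adjusted over the list alone; camera adjusted p = 0.15). CLDN7, a tight junction claudin, rose from 96.4 ± 2.86 to 182 ± 14.5 CPM and ESRP2, an epithelial splicing regulator, from 66.5 ± 0.309 to 109 ± 4.41 CPM. Of 33 integrin and focal adhesion genes, 5 rose and 12 fell, 17 passing when adjusted over the list alone (camera adjusted p = 0.27), with ITGB1, encoding integrin beta 1, falling from 2389 ± 52.5 to 859 ± 183 CPM. Of 13 fibroblast, endothelial and blood markers, 1 rose and 5 fell, 6 passing when adjusted over the list alone (camera adjusted p = 0.44). DCN, encoding decorin, fell from 72.2 ± 2.85 to 9.12 ± 2.39 CPM. LUM averaged 0.484 CPM in shSCRAM and had no count in either shBRG1 library, which makes it at least 7.53-fold lower against a floor of 3 counts over the pooled shBRG1 libraries, for counting error only. The covariate left 7 of the 22 junction calls and 7 of the 17 integrin calls in the same direction. It also left 3 of the 6 fibroblast, endothelial and blood calls. The medians there were 0.26, -0.23 and -0.39 in the order given, against 0.27, -0.16 and -0.30 without the covariate. The last 2 of these lists passed camera there.

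The authors' deposited table of changed genes was compared with this fit. It lists 1468 genes, 176 higher and 1292 lower in shBRG1 cells, all with adjusted p under 0.01 and at least a 2-fold change in that table. All 1468 passed the edgeR threshold here with the same sign. Conversely, 1443 of the 1701 genes that reached 2-fold at adjusted p under 0.01 here are in the authors' deposited table. Both come from the same libraries, so the overlap is not independent evidence. The authors' deposited table holds 29 of the AT-rich transcripts as lower and 0 of the GC-rich transcripts. Since it keeps only changes of at least 2-fold and the GC-rich list had a median log2 fold change of 0.38, that 0 owes much to the cutoff.

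The BRG1 ChIP-seq data describe where the protein was bound in parental MCF-10A cells. A single list of 15046 peaks was used, in hg19 coordinates, covering chromosomes 1 to 22 and X. Every peak was 267 bp wide, no peak overlapped its neighbour, and the score column held the same value throughout, so peaks could not be ranked. Peaks averaged 5.11 per Mb between the first and last peak of each chromosome. Chromosome 19 carried 11.4 peaks per Mb (675 peaks), chromosome 16 carried 9.55 (861 peaks), chromosome 17 carried 8.50 and chromosome 22 carried 7.76. Chromosome 8 carried 6.25, chromosome 20 carried 5.79 and chromosome 5 carried 5.74. The lowest values were 2.68 on X, 3.48 on chromosome 18 and 3.62 on chromosome 13. Peaks lay closer together than a uniform placement would put them. The median distance between neighbouring centres was 94.0 kb, against 124 to 132 kb in 100 simulated placements between the same ends. Neighbouring centres were nearer than 10 kb in 1472 of 15023 pairs, against 762 to 907 in the simulations. The simulated placements did not exclude assembly gaps, which lowers their density within the sequenced parts. The densest 1 Mb window, singled out after its value was seen, held 39 peaks on chromosome 16 from 30000001 to 31000000, where the median window with a peak held 4. The list has no replicate or control values, so no error can be given for these counts.

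**Figure D4:**
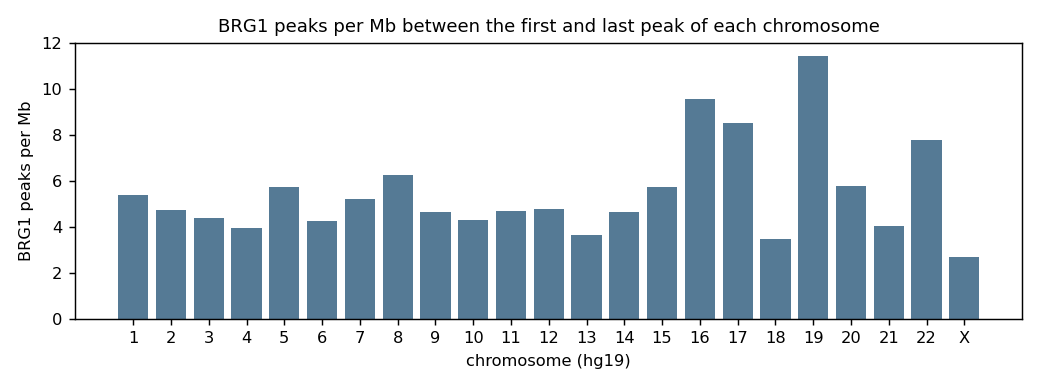
BRG1 peaks per Mb (vertical axis, starting at 0) between the first and last peak of each hg19 chromosome (horizontal axis), with a bar per chromosome. Chromosome 19 reached 11.4 peaks per Mb and X 2.68.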

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

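The composition covariate and the estimated correlation changed many calls, and leaving out a shSCRAM library changed the count of genes. Standard errors were wider under the covariate for the matrix, ribosomal protein and respiratory chain genes, so a lost call there need not mean a smaller change. The count of 7600 genes past the threshold stayed between 6513 (DESeq2) and 8179 (no filter beyond a count above 0) with other scalings, filters and tests, with unrounded counts, with thinned libraries and with a voom weight per group. A block for replicate number gave 7314. Without single libraries the count ran from 3311 (without shSCRAM replicate 1) to 10888 (without shBRG1 replicate 1); the lone library was then assumed to vary like the pair that stayed, and the pairs differed in spread (2.24% and 13.7%). It was 3456 with the shSCRAM libraries summed as 1 sample, where the wider shBRG1 pair alone set the spread, and 2119 with the composition covariate. Stricter thresholds gave 4602 genes (adjusted p under 0.01), 4508 (at least 1.5-fold) and 2081 (at least 2-fold).

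SMARCA4 stayed lower past the threshold in each alternative run. Of the gene lists, 13 passed, and 0 did with an estimated correlation. So few libraries leave too little to estimate that correlation from, so the 0 is not evidence against the lists. By fry 22 passed in 1 direction (11 shared) and 28 for changes in either direction. With the composition covariate 17 passed (11 shared), and those gained were EGF-MAPK, TGF-beta, integrins, basal markers, G2/M and the fibroblast, endothelial and blood markers. With the composition covariate 84 of the 138 named genes stayed the same, 50 lost their call and 3 changed sign without passing: CENPE (0.0359), CCNE2 (0.27) and RPS9 (-0.0193). The fitted value of LUM there (13.36) is no estimate, since LUM has no count in shBRG1. The ribosomal protein list had a median of 0.00010 there; the cause was not tested beyond the composition tests under the other observations. Without shSCRAM replicate 1, 8 named genes lost their call, and without shSCRAM replicate 2, 7 did. The overlap with the authors' table was 1468 genes, and 1415 with DESeq2. The peak count of 15046 did not change without unplaced contigs.

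The composition covariate, the summed libraries, thinning and the voom weight per group were chosen after seeing the data. The tests of peaks at promoters and of the higher-scoring peaks were not run. At the lowest depth, with all libraries thinned, 6660 of 13228 tested genes passed. In simulated counts the edgeR step called 70.8% of genes changed 1.5-fold, but depth was not varied there and both groups had the same spread.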

Other observations

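Mammary lineage markers moved in both directions. Of 18 luminal markers, 8 rose and 5 fell, 13 passing when adjusted over the list alone (camera adjusted p = 0.40). The simple epithelial keratin genes KRT8 and KRT18 rose, from 953 ± 10.1 to 1968 ± 221 CPM (SD, n = 2) and from 399 ± 1.27 to 787 ± 85.2 CPM, while AR, the androgen receptor gene, fell from 10.4 ± 0.258 to 3.17 ± 0.480 CPM. Of 22 basal and myoepithelial markers, 5 rose and 9 fell, 15 passing when adjusted over the list alone (camera adjusted p = 0.43). SFN, encoding 14-3-3 sigma, rose from 146 ± 1.84 to 276 ± 12.3 CPM and the basal keratin gene KRT5 from 3282 ± 56.2 to 4840 ± 675 CPM, while TAGLN, an actin-binding protein of contractile cells, fell from 26.8 ± 0.881 to 7.64 ± 0.0264 CPM. Of 27 epidermal differentiation genes, 8 rose and 9 fell, 17 passing when adjusted over the list alone (camera adjusted p = 0.64). The transglutaminase gene TGM1 rose from 20.0 ± 0.0652 to 46.5 ± 4.95 CPM and KRT10 fell from 273 ± 7.64 to 173 ± 5.57 CPM. The composition covariate left 6 of the 13 luminal, 7 of the 14 basal and 3 of the 17 epidermal calls in the same direction, and the basal list passed camera there. The AT-rich transcripts fell in the same libraries by a median of -1.61.

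Signalling and metabolic lists were also mixed. Of 32 EGF-MAPK and AP-1 genes, 5 rose and 14 fell, 23 passing when adjusted over the list alone (camera adjusted p = 0.11), with CCND1, encoding cyclin D1, falling from 274 ± 0.628 to 153 ± 7.92 CPM and JUN from 83.8 ± 3.19 to 45.7 ± 0.293 CPM. The EGF-MAPK list passed camera under the covariate, where its median went from -0.26 to -0.55. Of 31 p53 targets and CDK inhibitors, 8 rose and 12 fell, 20 passing when adjusted over the list alone. Their median was 0.06 while camera's direction was down (adjusted p = 0.90), and CDKN1A, encoding p21, was at 315 ± 11.1 and 326 ± 43.1 CPM and did not pass. Of 31 glycolysis and hypoxia genes, 16 rose and 7 fell, 26 passing when adjusted over the list alone (camera adjusted p = 0.094). The pyruvate kinase gene PKM rose from 3557 ± 51.3 to 5710 ± 674 CPM and ANGPTL4 fell from 257 ± 0.679 to 114 ± 5.23 CPM. This list passed camera without shBRG1 replicate 1 (median 0.41) and with no filter beyond a count above 0 (median 0.31), and under the covariate its median went from 0.32 to -0.05. Of 28 solute carriers and lipid handling genes, 6 rose and 11 fell, 17 passing when adjusted over the list alone (camera adjusted p = 0.48), with the amino acid transporter gene SLC7A2 falling from 22.96 ± 0.529 to 3.47 ± 0.0702 CPM. The covariate left 8 of the 19 EGF-MAPK and 2 of the 20 p53 calls in the same direction. It left 5 of the 23 glycolysis and 8 of the 17 solute carrier calls. The p53 median turned from 0.06 to -0.14, with 0 members higher and 3 lower. The solute carrier median turned from -0.21 to 0.15, with 9 members higher and 4 lower.

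Chosen only after the results were seen were the collagen test of the fibroblast explanation and the covariate and replicate difference tests of the matrix and respiratory chain genes, as were the composition lists.

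Large changes were mostly decreases: 88.7% of the calls of at least 2-fold were lower in shBRG1 cells. Over 3 other scalings the lowest share was 88.2%. They moved the median of all genes by -0.11 (library totals), 0.0115 (relative log expression) and 0.00032 (upper quartile) on the log2 scale. None could have lowered the share much, so they do not decide whether scaling contributed. After thinning all libraries and keeping genes of at least 10 CPM, the share was 88.2% (747 of 847 calls). That argues against the lower depth of shBRG1 replicate 1. With the composition covariate the share was 66.8% (447 lower and 222 higher), between bounds set before that fit, although the covariate and its lists were chosen after seeing the data. Base composition or library preparation therefore cannot be told apart from the knockdown here, since the composition index separates the groups and its slope rests on the 2 shBRG1 libraries.

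Matrix and mesenchymal genes were lower, with a median of -0.87 over 78 members. Stromal cells in the shSCRAM cultures would bring their abundant collagens, but COL1A1, COL1A2 and COL3A1 together fell by 0.251 CPM (scaled over the unfiltered table) while FN1 fell by 3168 CPM, which is 0.00792% (at most 0.102% over single libraries). That sum joins opposite moves: COL1A1 had a log2 fold change of 0.46 and did not pass, and COL1A2 fell by -1.37. Of 6 tested fibroblast markers, 4 were lower past the threshold and 0 higher. Their median was -1.29 (interquartile range -2.04 to -0.53), which alone lay between the bounds set before that test. DCN, outside this set, had a log2 fold change of -2.94. The composition trend as the whole cause would need these genes lower in shBRG1 replicate 2 than in replicate 1 by a median of -0.38. These genes were instead higher by 0.21 (SD of the list medians 0.16). With the covariate their median was -1.20, although lower calls went from 51 to 43. The covariate slope rests almost wholly on the same difference between the 2 shBRG1 libraries, so that median is not separate evidence. A lower level in the knockdown cells themselves may be a candidate explanation and remains a hypothesis.

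Ribosomal protein and respiratory chain genes were higher in 84.9% of 93 members. Over 3 other scalings the lowest share was 78.5%. The largest move of the median of all genes, -0.11 on the log2 scale with library totals, argues only against a scaling error of that size. Base composition cannot be told apart from an unequal response of the 2 shBRG1 libraries: the GC-rich list exceeded the AT-rich list by 1.99 between groups and by 0.79 between those libraries, but their difference follows the fold change across genes (r = 0.64) and the lists were written after fold changes were seen. With the covariate the respiratory chain median went from 0.60 to 0.34 and that of the ribosomal protein genes to 0.00010. For both it stays open, as does an effect of the knockdown: the respiratory chain departed from the replicate difference the trend would need by -0.14, less than the SD of the list medians.

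Neighbouring genes had similar fold changes. Across 13265 tested genes in chromosome order, which are not independent replicates, the correlation was 0.33 for adjacent genes and 0.22 for genes 5 places apart, where the highest of 1000 permutations gave 0.0278 and 0.0289. A domain-wide effect could give this, but the difference between the 2 shBRG1 libraries also correlated at 5 places (0.104, highest permuted 0.0288), as base composition shared by neighbours or an unequal response of these libraries might. Under the covariate the correlation was 0.0217 for adjacent genes and -0.0096 at 5 places, both within the permuted range, but the rank correlation of adjacent genes was 0.0546, above the highest of 200 permutations (0.0199). These explanations cannot be told apart here, since the replicate difference follows the fold change.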
